A study of Homo sapiens with 3 samples.

How the data were processed

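RNA from MDA-MB-231 cells, a human breast cancer line, was labelled with biotin and hybridised to Affymetrix oligonucleotide arrays, per the labels' protocols. The labels describe 3 cultures, each with 1 array: vehicle (0.1% ethanol), estradiol at 1 µM and tamoxifen at 1 µM, all for 3 h after 4 h in medium with 10% charcoal-stripped serum. By the labels each group therefore held 1 array, although the vehicle values may be means of 2 values, as weighed below. The number of arrays limits the precision of every value. No replicate spread, interval or p-value can be given.

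The deposited log2 values cover 54675 probe sets and 3 columns, and robust multi-array averaging (RMA, version not stated) is named in the submitters' processing notes. The deposited values are not RMA levels as such. Their column medians were -0.04 for vehicle, -0.02 for estradiol and -0.02 for tamoxifen, and their SDs over probe sets were 0.20, 0.47 and 0.46. Values were therefore taken to be centred per probe set on a baseline that is none of the 3 columns. What that baseline was, and whether any column pooled several arrays, is not given in the sources used here. Base 2 was taken from RMA and is not stated with the values. The direction of the values (higher meaning more RNA) was also assumed and not stated. The 3 comparisons used differences between columns of 1 probe set, because a baseline shared by the columns cancels in them. It need not cancel where the vehicle values were doubled, or in slopes and SDs of the columns themselves, so those values depend on the unstated baseline. Nor need it cancel in plain differences from vehicle if the vehicle values are means that include 1 value near the baseline, as weighed below.

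A floor of 6 (log2) on the level had been planned and could not be applied to centred values. It was replaced, after the data were examined, by brightness bands read from the binary steps on which the deposited numbers lie. A single-precision level between 8 and 16 is stored in coarser steps than one between 4 and 8, 2 and 4, or below 2, and a difference keeps the finer step. Each probe set was put in the band of its finest step over the 3 columns, the vehicle column being shifted by 1 step because its steps were finer. Probe sets in the 4 to 8 band or brighter were kept. Of 117 probe sets for ribosomal protein genes, 105 lay above this floor (89.7%), against 14 of 107 for olfactory receptor genes (13.1%) and 0 of 20 for bitter taste receptor genes. Between pairs of probe sets of 1 gene, the estradiol minus vehicle differences correlated with r = 0.42 across 1084 genes in the brightest band and with r = 0.03 across 1208 genes in the dimmest. For tamoxifen minus estradiol r was 0.34 in the brightest band, 0.24 in the 4 to 8 band and 0.02 in the dimmest.

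Probe sets were named through the table of platform annotation supplied with the values: 41097 had 1 gene symbol, 1801 had several and 11777 were not in the table. Only those with 1 symbol were named, and the others were left out of all gene results. Symbols were looked up in a table of current RefSeq genes and 0 needed updating. Of 19775 named genes, 12092 lay above the floor, 5100 in the brightest band and 6992 in the 4 to 8 band. The planned choice of the probe set with the highest mean was not possible without levels. The value of a gene was the mean over its probe sets in its brightest band, and for 3442 genes this averaged several. Some genes of the lists, such as those without a probe set of their own name in the table, were not analysed here.

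The 3 comparisons were differences of log2 values: estradiol minus vehicle, tamoxifen minus vehicle, and tamoxifen minus estradiol. No test was run, and genes were picked by a size rule of 1.5-fold. The other choices were made before the data were examined, apart from those said here to come later. They include 43 gene lists drawn from textbook knowledge. For each list the median difference over members above the floor (at least 5) was set against 10000 random lists of the same size, drawn to match its members in brightness band and in having 1 or several probe sets. Matching on mean expression, as planned, needs levels. A list is said to stand apart when its percentile was under 1 or over 99, which describes these arrays and does not test the treatments. With 129 list comparisons, about 2.58 would pass by chance if the members of a list varied independently. Members of 1 list may vary together, some lists share genes, and the 3 comparisons are not independent. The number that would pass by chance in these arrays is therefore not known. The genes named are the 12 largest and 12 smallest differences per comparison, up to 4 members with the largest absolute difference of each list described, and the genes ESR1, ESR2, GPER1, PGR, GAPDH and ACTB whatever their values. Other members, where named, were chosen after their values were seen. The correlation of the ligands' differences was set beside 100 shuffles of each gene's 3 values among the arrays, since both differences share the vehicle array. Array gauges were the hybridisation spikes, the poly-A spikes, the 5' and 3' probe sets of control genes, and reference genes.

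Alternatives were centring of each array on its median, no floor, a floor of 8, the mean of all probe sets, leaving out cross-reacting probe set types, probe sets of 1 gene all in the same direction, a 2-fold rule, a rule scaled to brightness, and Spearman's correlation. The cross-reacting types are here all probe sets with names ending in _x_at or _s_at. Whether each of them does cross-react was not examined, and some may measure 1 gene only. Leaving them out also reduced the genes from 12092 to 9165, so a change in that setting need not come from cross-reaction. Doubling of the vehicle values and centring within brightness bands were added after the data were examined. The scripts were tested on simulated data for estradiol against vehicle, with known bands, 200 planted genes (195 of them among 12889 genes above the floor) differing by 1 on the log2 scale, and a noise SD of 0.2 per array. Of the simulated probe sets, 84.3% were returned to their band, 98.6% of those above 4 were kept, and 8.48% of those below 4 were wrongly kept. The size rule found 92% of the planted higher genes, 96.8% of the planted lower genes and 1.25% of the other genes. The simulated vehicle was the mean of 2 arrays with the same noise per array. These shares therefore do not carry over to differences between single arrays, such as tamoxifen minus estradiol, where noise is larger. No gene's vehicle signal was reduced in the simulation, so a vehicle column holding part of its signal was not imitated. The shares are therefore not rates of false calls for the real comparisons with vehicle either. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9.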

Results

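Gene expression was measured in MDA-MB-231 cells, a breast cancer line of basal type that is commonly classed as negative for the estrogen receptor, after 3 h with vehicle, estradiol or tamoxifen, both ligands at 1 µM. Estradiol is the main natural estrogen, and tamoxifen is an antiestrogen used against breast cancer. The series title puts the question as the effect of tamoxifen on early gene expression. By the labels there was 1 array per group and no replicate, so each difference below compares 3 columns pairwise and has no error estimate. Differences are on the log2 scale, and 12092 genes lay above the brightness floor. The values are centred on an unstated baseline, and their scale and direction are assumed. The vehicle values had less than 0.5 of the spread of the ligand values across genes (SD 0.21 against 0.49 and 0.49), so differences from vehicle are also given with the vehicle value doubled, a setting chosen after the data were examined. In that setting the unstated baseline need not cancel. If the vehicle column holds only about 0.5 of its signal, as weighed below, the baseline need not cancel in plain differences either. Which of the settings is closer to the true differences was not tested.

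Of the receptors, ESR1 had 1 of 9 probe sets above the floor. That probe set differed by 0.04 between estradiol and vehicle, by -0.70 between tamoxifen and vehicle, and by -0.75 between tamoxifen and estradiol. With the mean of all its probe sets the last 2 differences were 0.03 and 0.06. No probe set of ESR2 (6 probe sets) or PGR (2 probe sets), a classical target of the estrogen receptor, lay above the floor. The membrane estrogen receptor GPER1 had 1 of 2 probe sets above the floor, which differed from vehicle by 0.03 with estradiol and by -0.05 with tamoxifen. Its other probe set, below the floor, differed by 0.07 and -0.57. The list of classical estrogen-induced genes did not stand apart with estradiol (median 0.09 over 19 genes, percentile 79.2) or with tamoxifen (0.08, percentile 75.8). Among its members CA12 was higher with estradiol by 0.80, HSPB8 by 0.73 and MYC by 0.69, and CCND1 was lower at -0.59. None of these 4 passed 1.5-fold once the vehicle was doubled (0.56, 0.01, 0.54 and -0.42). The list of estrogen-repressed genes had a median of 0.22 with estradiol and 0.02 with tamoxifen over 8 genes, at percentiles 94.2 and 48.4. The reference genes GAPDH and ACTB differed from vehicle by -0.07 and -0.05 with estradiol and by -0.15 and -0.14 with tamoxifen. The list of 18 reference genes had medians of 0.13 and 0.00 (percentiles 89.6 and 34.0), and 3 of its genes passed the size rule upward with each ligand. These were PGK1 (0.83 and 0.95), HPRT1 (0.71 and 0.78) and B2M (0.60 and 0.71), of which HPRT1 with tamoxifen (0.62) alone passed it with the vehicle doubled.

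With estradiol, inflammatory genes were among those furthest above the vehicle array. CXCL8, which encodes a neutrophil-attracting chemokine, was 4.70-fold higher (log2 difference 2.23) and IL6, an inflammatory cytokine, was 4.34-fold higher (2.12). PTGS2, the inducible cyclooxygenase, was higher by 1.99 and the chemokine gene CXCL2 by 1.87. Of the 12092 named genes above the floor, 724 were at least 1.5-fold higher and 338 at least 1.5-fold lower, and 144 and 34 passed 2-fold. Probe sets above the floor without a single gene name leaned the other way, with 168 higher and 501 lower at 1.5-fold.

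The other genes with the largest differences were CDH11, a mesenchymal cadherin (2.87), RNF128 (2.52), CEMIP (2.44), the MHC class II genes HLA-DRA (2.44) and HLA-DPA1 (2.23), SDR16C5 (2.33), the collagen gene COL4A5 (2.21), SORL1 (2.21) and the cystatin gene CST1 (2.04). With the vehicle value doubled, CXCL8 (2.52), IL6 (1.75), PTGS2 (1.22) and CXCL2 (2.55) stayed past 2-fold, while CDH11 (0.11), HLA-DRA (0.57), HLA-DPA1 (0.31), SDR16C5 (0.58) and CST1 (0.05) did not pass the 1.5-fold rule. RNF128 (0.85), CEMIP (0.65), COL4A5 (0.88) and SORL1 (0.98) passed it by less. The genes with the smallest differences were LINC01296 (-2.08), SNCAIP (-2.02), DUXAP10 (-1.76), KISS1 (-1.62), the ribosomal protein gene RPL27A (-1.53), ZNF628 (-1.28), PIDD1 (-1.28), TAF15 (-1.28), HCRP1 (-1.26), ALMS1 (-1.26), BAG2 (-1.24) and LOC105379426 (-1.20). With the vehicle doubled, SNCAIP (0.04) and KISS1 (-0.07) no longer differed past the rule. Without the cross-reacting probe set types CEMIP was at 0.28, PIDD1 at -0.43 and ALMS1 at 0.10, and with all probe sets averaged ALMS1 was at -0.32 and BAG2 at -0.19.

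Of the 43 lists, 17 stood apart in the estradiol comparison. The interferon list had a median of 0.54 (percentile 100), with 10 of 22 genes past the rule upward, among them CXCL11 (1.46), IFI27 (0.98), RIGI (0.88) and OAS2 (0.81). With the vehicle doubled its median was 0.18 and it did not stand apart (percentile 92.3). The NF-kB and inflammatory list had a median of 0.46 (percentile 100) with 10 of 21 genes higher and 1 lower, and doubling gave 0.66. The hypoxia and glycolysis list had a median of 0.42 (percentile 100) with 11 of 27 genes higher, led by the angiogenic factor VEGFA (1.48), NDRG1 (0.99), the glucose transporter SLC2A1 (0.87) and BHLHE40 (0.86). The cAMP and CREB list had a median of 0.41 over 12 genes (percentile 99.9), with the nuclear receptor gene NR4A2 at 1.04, FOS at 1.0 and the phosphodiesterase gene PDE10A at 0.88. Immediate early genes had a median of 0.26 over 27 genes (percentile 99.98), with EREG, an EGFR ligand, at 1.69 and the stress factor ATF3 at 0.77. The hypoxia (0.37), cAMP (0.49) and immediate early (0.36) lists also stood apart with the vehicle doubled.

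Other stress and signalling lists also stood apart. The ATF4 and amino acid list had a median of 0.32 over 21 genes (percentile 99.98), with NUPR1 at 1.51, DDIT4 at 1.11 and asparagine synthetase ASNS at 0.99. Feedback regulators of the ERK pathway had a median of 0.36 over 19 genes (percentile 100), with SPRY2 at 0.86 and SPRED2 at 0.76. The aryl hydrocarbon receptor list had a median of 0.35 over 10 genes (percentile 99.6), with CYP1B1 at 1.70 and AHR itself at 0.62. Glucocorticoid response genes had a median of 0.29 over 13 genes (percentile 99.3), with SCNN1A at 0.91 and TSC22D3 at 0.78. The TGF-beta list had a median of 0.26 over 19 genes (percentile 99.5), with SNAI2 at 1.20, SMAD7 at 1.08 and ID1 at -0.89. The matrix and invasion list stood at 0.29 over 23 genes (percentile 99.96), with ITGA2 at 0.83 and MMP1 at -0.68. Basal breast and MDA-MB-231 markers stood at 0.26 over 17 genes (percentile 99.5), with CTSL at 0.81. Autophagy and lysosome genes stood at 0.22 over 25 genes (percentile 99.6), with LAMP2 at 0.90, and p53 response genes at 0.21 over 20 genes (percentile 99.1), with GDF15 at 1.28. With the vehicle doubled, the ERK (0.21), ATF4 (0.23), aryl hydrocarbon receptor (0.22), glucocorticoid (0.24), matrix (0.07), basal marker (0.23) and p53 (0.12) lists no longer stood apart.

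Downward, histones had a median of -0.28 over 8 genes (percentile 0.48), with the linker histone gene H1-2 at -0.80 and H2AX at -0.63. G1/S cell cycle genes had a median of -0.20 over 26 genes (percentile 0.03), with MCM5 at -0.59 and E2F2 at -0.54, while CCND2 was higher by 1.0. The G1/S median was 0.08 with the vehicle doubled, and that of histones -0.64, with 5 of the 8 genes lower past the rule against 2 as deposited. Cholesterol synthesis genes had a median of -0.17 over 19 genes (percentile 0.74), with MVD at -0.62 and HSD17B7 at -0.52, and -0.09 (percentile 0.805) with the vehicle doubled. Of the 74 distinct genes of these 17 lists that passed the size rule with estradiol, 33 passed it in the same direction with the vehicle doubled. Of the upward examples above, CXCL11 (0.23), IFI27 (0.31), OAS2 (0.38), SLC2A1 (0.41), ATF3 (0.48), NUPR1 (0.36), SPRED2 (0.52), CYP1B1 (0.49), AHR (0.50), SCNN1A (0.42), TSC22D3 (0.58), SNAI2 (0.37), SMAD7 (0.54), ITGA2 (0.49), LAMP2 (0.53), GDF15 (0.54) and CCND2 (0.32) did not. Of the downward ones, MMP1 (-0.36), ID1 (0.01) and MCM5 (0.10) did not. Of the 17 lists, those of NF-kB and hypoxia stood apart under every alternative. Without the cross-reacting probe set types the immediate early (0.21), ATF4 (0.24), aryl hydrocarbon receptor (0.34), TGF-beta (0.26), matrix (0.14), basal marker (0.19), autophagy (0.04), p53 (0.17) and cholesterol synthesis (-0.09) lists did not, and with all probe sets averaged the histone (-0.21), G1/S (-0.11), TGF-beta (0.19), aryl hydrocarbon receptor (0.25), basal marker (0.20) and autophagy (0.04) lists did not. With a floor of 8 the ATF4 (0.11), aryl hydrocarbon receptor (0.35), glucocorticoid (0.28), basal marker (0.23), autophagy (0.22), p53 (0.25) and cholesterol synthesis (-0.14) lists did not stand apart. Nor did the aryl hydrocarbon receptor (0.22) and histone (-0.20) lists with no floor, or the p53 (0.19) and cholesterol synthesis (-0.18) lists with centring within brightness bands. Leukocyte markers had a median of -0.16 over 6 genes (percentile 10.0) and fibroblast and endothelial markers 0.07 over 5 genes (percentile 64.0). The poly-A spikes, bacterial RNAs added before labelling, were 2.06-fold brighter on the estradiol array than in the vehicle values (median difference 1.04 over 24 probe sets, and 0.47 with the vehicle doubled), and the hybridisation spikes differed by 0.18.

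With tamoxifen, histone genes had the lowest list median against vehicle and cAMP-responsive genes the highest. H2AC6 was 3.61-fold lower than on the vehicle array (-1.85) and H1-2 was 3.35-fold lower (-1.74). NR4A2 was 3.47-fold higher (1.79) and BMP2, a bone morphogenetic protein, was 3.86-fold higher (1.95). At least 1.5-fold differences were seen upward in 848 genes and downward in 539, and 157 and 63 passed 2-fold.

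The largest differences upward were those of CDH11 (3.01), RNF128 (2.89), SORL1 (2.38), CEMIP (2.36), COL4A5 (2.07), HLA-DPA1 (2.05), BMP2 (1.95), CYP1B1 (1.95), RADX (1.93), the integrin gene ITGB8 (1.93), EREG (1.91) and HLA-DRA (1.90). With the vehicle doubled, BMP2 stood at 1.89, EREG at 1.35, ITGB8 at 1.34, RNF128 at 1.22, SORL1 at 1.16 and RADX at 1.07, while CDH11 (0.25), CEMIP (0.57), HLA-DPA1 (0.14) and HLA-DRA (0.03) did not pass the 1.5-fold rule. COL4A5 (0.73) and CYP1B1 (0.74) passed it by less. Without the cross-reacting probe set types CEMIP stood at 0.46. The largest differences downward were those of RIMS2 (-1.89), C6orf141 (-1.87), H2AC6, KISS1 (-1.76), H1-2, the arginase gene ARG2 (-1.74), ZNF114 (-1.70), the ribosomal protein gene RPLP2 (-1.63), H1-10 (-1.56), SRGAP2 (-1.52), MSLN (-1.46) and AP1M2 (-1.45). Doubling left C6orf141 (-1.67), H2AC6 (-2.36), H1-2 (-1.68), ARG2 (-1.79), RPLP2 (-1.62), SRGAP2 (-1.45), H1-10 (-1.21) and MSLN (-1.01) past 2-fold, AP1M2 (-0.99), ZNF114 (-0.93) and RIMS2 (-0.75) past 1.5-fold, and KISS1 (-0.20) within it.

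The plot of ranked genes sets both versions of each vehicle comparison side by side.

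**Figure D1:**
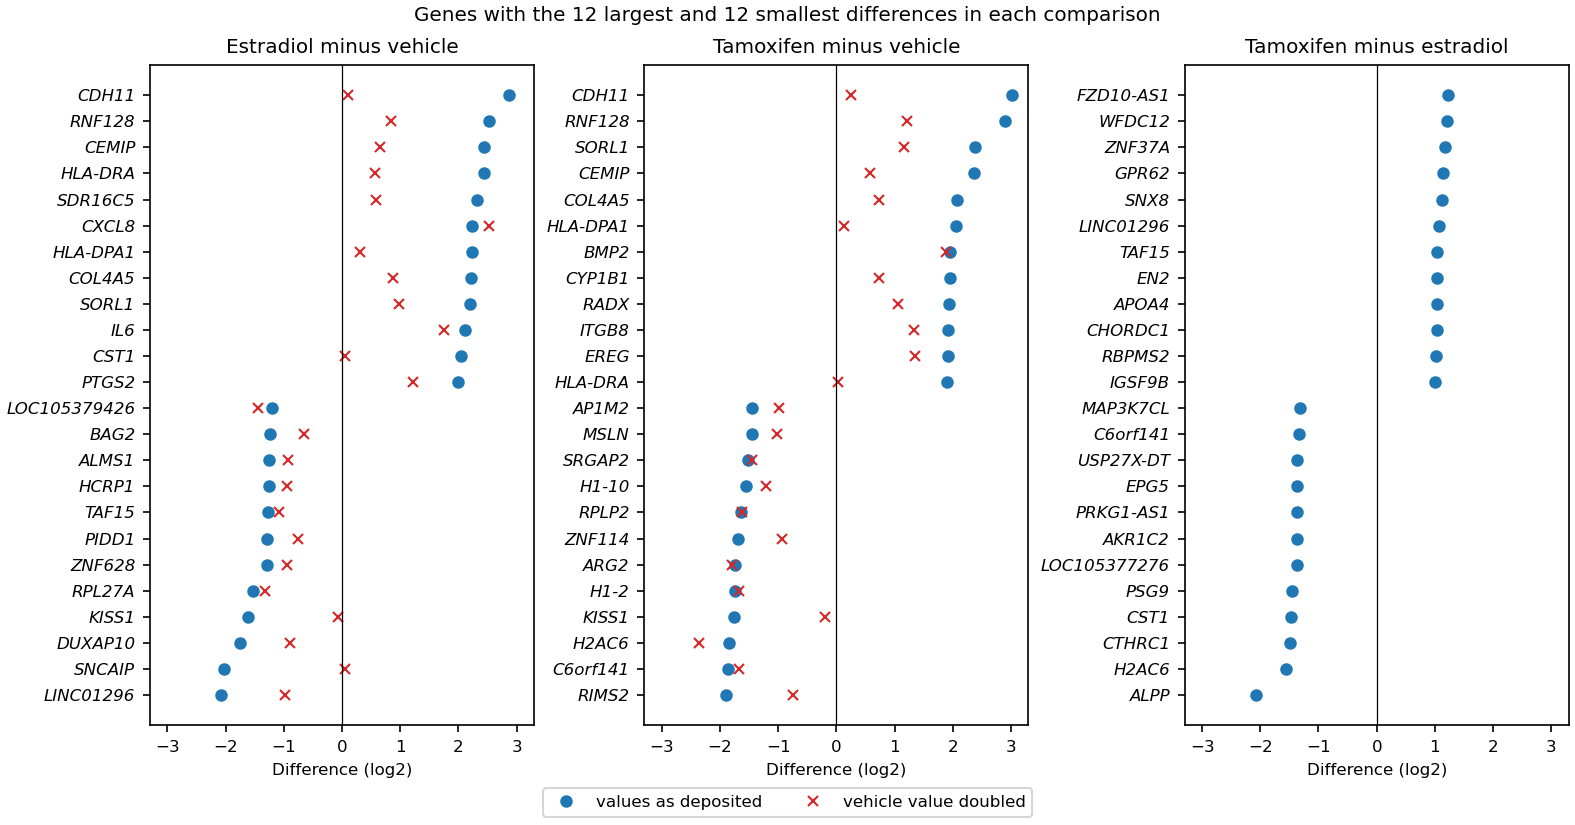
Log2 differences (x axis) of the 12 genes with the largest and the 12 with the smallest difference in each of the 3 comparisons, with 1 array per group and no error bars. Circles are the values as deposited and crosses those with the vehicle value doubled, under which CXCL8 stands at 2.52 and CDH11 at 0.11 in the estradiol comparison.

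With tamoxifen, 7 lists stood apart. Histones had a median of -1.04 over 8 genes (percentile 0.00), with 7 of the 8 lower past the rule, including H2BC21 (-1.14) and H2BC5 (-1.14). Cholesterol synthesis genes had a median of -0.34 over 19 genes (percentile 0.01), with FDPS at -0.74, HSD17B7 at -0.73, HMGCS1 at -0.59 and MSMO1 at -0.56. The cAMP and CREB list had a median of 0.54 (percentile 100) with 5 of 12 genes higher, among them PDE10A (1.21), the coactivator gene PPARGC1A (0.89) and FOS (0.82). Circadian genes had a median of 0.43 over 11 genes (percentile 99.8), with BHLHE41 at 1.10, BMAL1 at 0.98 and PER2 at 0.61. The hypoxia list had a median of 0.40 over 27 genes (percentile 100), with P4HA1 at 1.20 and VEGFA at 1.14. The aryl hydrocarbon receptor list stood at 0.35 over 10 genes (percentile 99.6), with CYP1B1 and AHR (1.10) leading, and the ERK feedback list at 0.32 over 19 genes (percentile 99.9), with SPRY2 at 1.11 and DUSP6 at 0.71. Of these 7 lists, the aryl hydrocarbon receptor list (0.21) alone no longer stood apart with the vehicle doubled. Of their 35 distinct genes past the size rule, 22 passed it in the same direction with the vehicle doubled, and FDPS (-0.55), PPARGC1A (0.58), VEGFA (0.33) and DUSP6 (0.48) did not. Without the cross-reacting probe set types the cholesterol synthesis (-0.18), circadian (0.25) and aryl hydrocarbon receptor (0.36) lists did not stand apart, and 4 histone genes were left, too few for a list. The ERK (0.23) and aryl hydrocarbon receptor (0.35) lists did not stand apart with a floor of 8, which left 4 genes each of the cAMP and circadian lists, nor did the aryl hydrocarbon receptor list (0.22) with all probe sets averaged. The interferon list had a median of 0.15 (percentile 94.1) as deposited and of -0.25 (percentile 0.01) with the vehicle doubled. The NF-kB list had a median of 0.12 (percentile 88.3), although PTGS2 (1.62), CXCL8 (1.53), CXCL1 (1.37) and IL6 (1.31) were all higher.

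The poly-A spikes were 1.83-fold brighter on the tamoxifen array than in the vehicle values (median 0.87, and 0.39 with the vehicle doubled) and the hybridisation spikes differed by 0.10. Leukocyte markers had a median of 0.09 (percentile 70.7) and fibroblast and endothelial markers -0.17 (percentile 17.0).

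Both ligands differed from vehicle in many of the same genes. At the 1.5-fold rule, 441 genes were higher with both ligands and 159 lower with both, and 3 went opposite ways. Independent lists would share 50.8 and 15.1 genes, and shuffling each gene's values among the 3 arrays gave means of 192 and 107, with highest counts of 217 and 128. Across genes, which are not independent replicates, the 2 differences correlated with Pearson's r = 0.73 and Spearman's rho = 0.69, against a mean of 0.50 after shuffling (0.48 to 0.52). The covariance was 0.10, against 0.06 after shuffling. With 1 vehicle column the controls could not be split, so part of the excess may come from the shared vehicle values. Shuffling also treats the 3 columns as alike, while the SD across genes was 0.21 for vehicle and 0.49 for each ligand. An excess over the shuffles could therefore arise from the narrower vehicle column alone. With estradiol or tamoxifen as the shared array, r was 0.26 and 0.47.

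**Figure D2:**
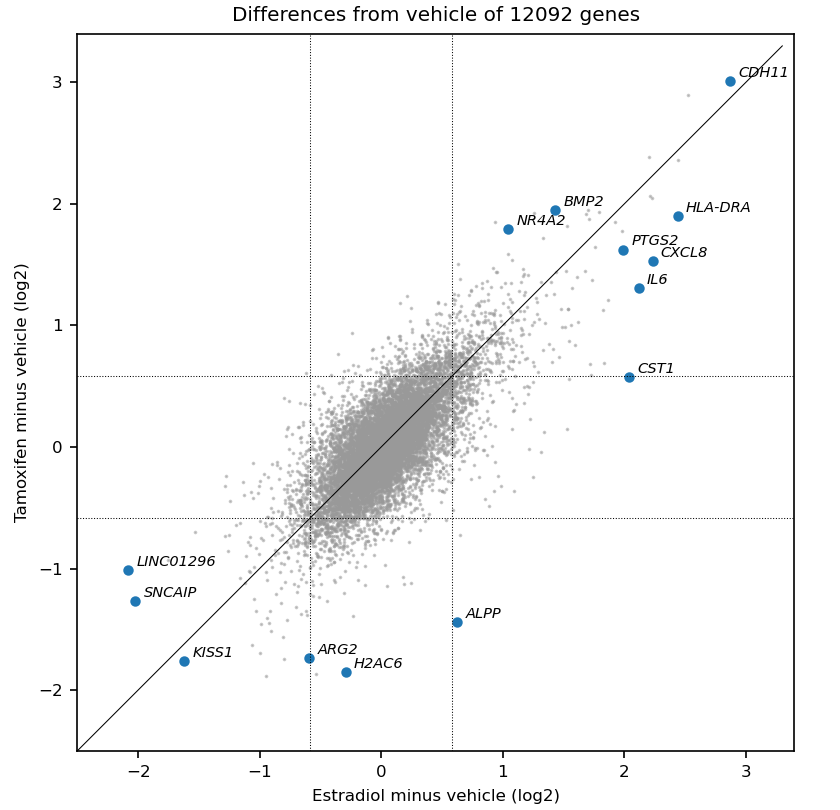
Log2 difference from vehicle with tamoxifen (y axis) against that with estradiol (x axis), 1 point per gene over 12092 genes, with selected genes in blue, dotted lines at 1.5-fold and a line of equality. CDH11 lies at 2.87 and 3.01 near the line, and ALPP and H2AC6 lie below it.

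Compared directly with estradiol, tamoxifen gave lower values of histone, interferon and inflammatory genes. ALPP, the placental alkaline phosphatase, was 4.19-fold lower on the tamoxifen array (-2.07), H2AC6 was 2.94-fold lower (-1.56) and the adhesion molecule gene ICAM1 was 2.32-fold lower (-1.21). IFIT2, an interferon-induced gene, was 2.08-fold lower (-1.06). This comparison does not use the vehicle values. Across all genes, 195 were at least 1.5-fold higher and 277 at least 1.5-fold lower with tamoxifen, and 12 and 34 passed 2-fold.

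Other genes lower with tamoxifen were CTHRC1 (-1.50), CST1 (-1.46), the pregnancy-specific glycoprotein gene PSG9 (-1.45), LOC105377276 (-1.37), the steroid-metabolising reductase gene AKR1C2 (-1.37), PRKG1-AS1 (-1.37), EPG5 (-1.36), USP27X-DT (-1.36), C6orf141 (-1.33) and MAP3K7CL (-1.32). ALPP, CST1, PSG9, AKR1C2 and the histone genes have near-identical relatives that can share probe signal. The genes highest with tamoxifen were FZD10-AS1 (1.22), WFDC12 (1.20), ZNF37A (1.18), GPR62 (1.14), SNX8 (1.12), LINC01296 (1.07), TAF15 (1.04), EN2 (1.04), APOA4 (1.03), the HSP90 cochaperone gene CHORDC1 (1.03), RBPMS2 (1.02) and IGSF9B (1.0). With all its probe sets averaged, TAF15 stood at 0.23.

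Of the lists, 9 stood apart between the ligands. Histones had a median of -0.81 (percentile 0.00), with 5 of 8 genes lower past the rule, including H2BC21 (-1.18), H2BC5 (-1.0) and H1-2 (-0.94). The interferon list had a median of -0.42 over 22 genes (percentile 0.00), with 7 lower and 0 higher past the rule, among them OASL (-0.89), IFIT1 (-0.78) and CXCL11 (-0.72). The NF-kB list had a median of -0.36 over 21 genes (percentile 0.00), with 5 lower and 0 higher, including IL6 (-0.81), RELB (-0.74) and CXCL8 (-0.70). The ATF4 list had a median of -0.32 over 21 genes (percentile 0.00), with 6 lower, led by CHAC1 (-1.0), ATF3 (-0.78) and PPP1R15A (-0.65), and 1 higher, STC2 (0.75). Glucocorticoid response genes stood at -0.30 over 13 genes (percentile 0.06), with CRISPLD2 at -0.57 and TSC22D3 at -0.47. Metallothioneins and metal response genes stood at -0.24 (percentile 0.33), with MT1E at -0.39 and MT1X at -0.37, and none of the 8 passed the size rule. Cholesterol synthesis genes stood at -0.21 over 19 genes (percentile 0.07), with HMGCS1, an early enzyme of the pathway, at -0.86. Autophagy and lysosome genes stood at -0.15 over 25 genes (percentile 0.90), with MAP1LC3B at -0.49. Nuclear receptor coregulators had a median of 0.21 over 10 genes (percentile 99.3), of which PPARGC1A (0.84) alone passed the rule, PPARGC1B stood at 0.49 and CITED2 (-0.40), PHB2 (-0.14) and PELP1 (-0.13) were below 0. Of these 9 lists, the interferon and NF-kB lists stood apart under every alternative. Without the cross-reacting probe set types the cholesterol synthesis (-0.01), autophagy (-0.07), glucocorticoid (-0.28) and coregulator (0.19) lists did not, and the histone (4 genes) and metallothionein (2 genes) lists were too short. With a floor of 8 the ATF4 (-0.08), autophagy (-0.15), glucocorticoid (-0.25) and coregulator (0.06) lists did not stand apart, nor did the last 3 with all probe sets averaged (-0.09, -0.12 and 0.16), or the coregulator list with no floor (0.19).

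**Figure D3:**
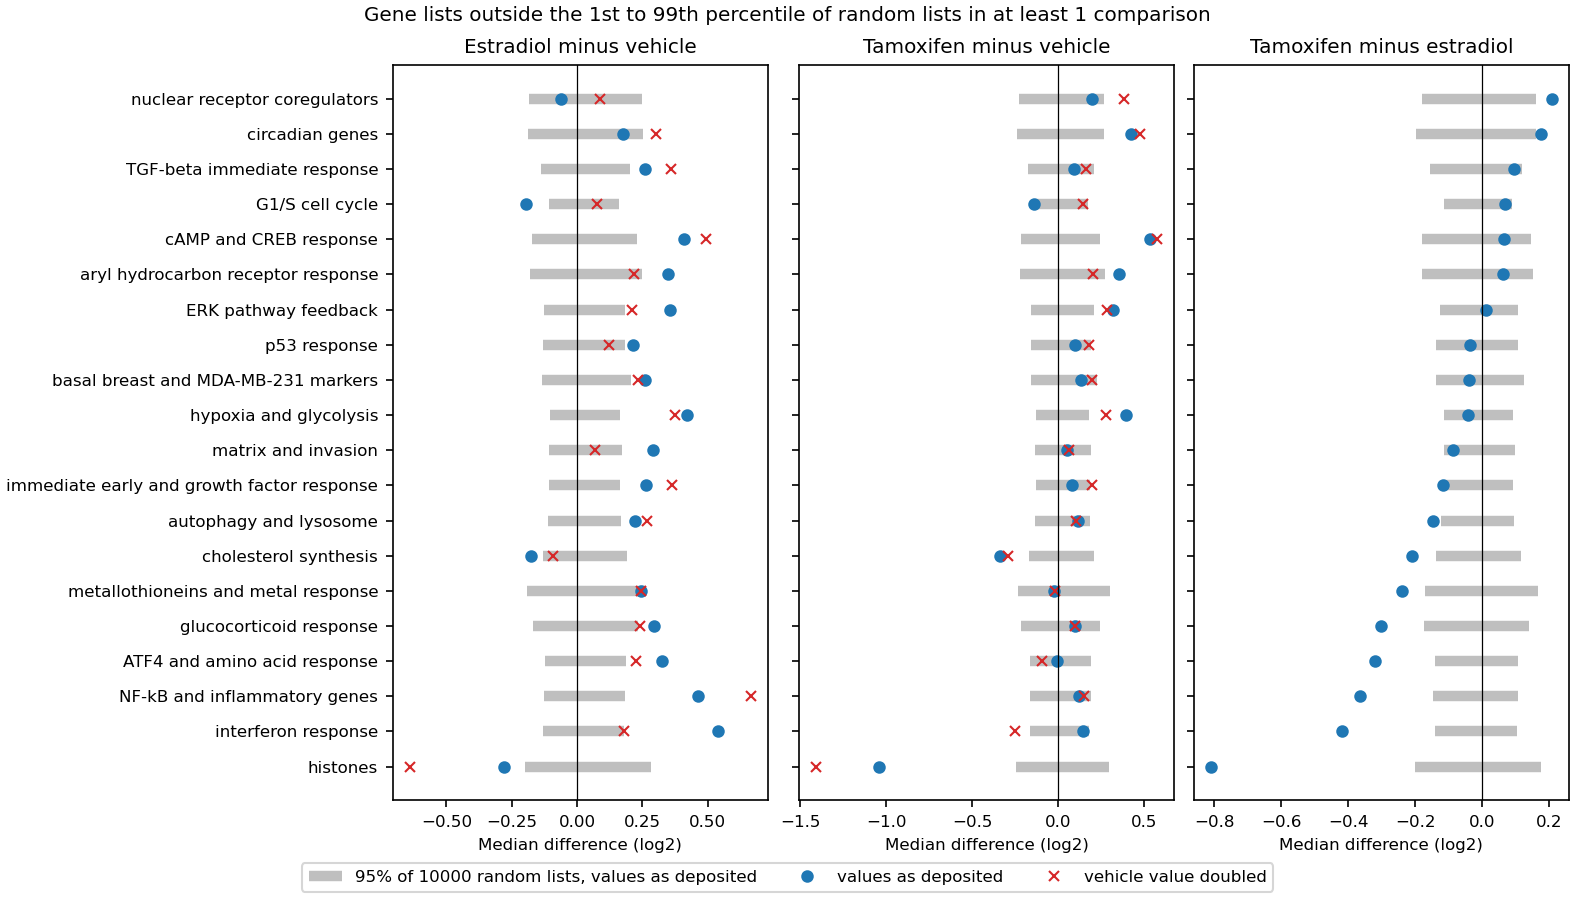
Median log2 difference (x axis) of each gene list that stood apart in at least 1 of the 3 comparisons, with 1 array per group. Circles are medians of the values as deposited, crosses those with the vehicle value doubled, and grey bars hold 95% of the medians of 10000 random lists of the values as deposited. Histones lie lowest, at -0.81, between tamoxifen and estradiol.

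Cell cycle lists did not stand apart between the ligands, with medians of 0.07 for G1/S (percentile 94.4) and 0.05 for G2/M (percentile 87.4). Leukocyte markers differed by a median of 0.01 (percentile 62.7) and fibroblast and endothelial markers by -0.07 (percentile 33.7). The poly-A spikes differed by -0.17 and the hybridisation spikes by -0.12. The 5' probe set of ACTB was lower against its 3' probe set on the tamoxifen array than on the estradiol array by a difference of -0.94, while the same quantity for GAPDH was -0.11. Where a probe set was past 1.5-fold between the ligands, another probe set of the same gene went the same way in 71.0% of 138 genes for lower and 65.1% of 129 genes for higher values, against 50.9% and 49.1% over all genes with several probe sets. The corresponding shares against vehicle were 80.6% and 62.9% for higher and lower with estradiol, and 86.2% and 74.8% with tamoxifen. Between the ligands, the other probe set itself passed 1.5-fold in 14.5% for lower and 8.5% for higher values. Over all genes with several probe sets these shares were 2.8% and 2.5%. Against vehicle the other probe set passed 1.5-fold in 27.3% and 11.2% for higher and lower with estradiol, and in 34.5% and 23.4% with tamoxifen. The shares over all genes with several probe sets were there 7.4% and 5.1% with estradiol, and 8.2% and 6.0% with tamoxifen.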

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

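The tests in this part were chosen after the values they bear on had been seen, except the share of shared genes left with the vehicle doubled. Controls outside the gene measurements stood out, in that the poly-A spikes differed from the vehicle values by a median of 1.04 with estradiol and 0.87 with tamoxifen. Among 3842 probe sets above the floor without a single gene name, which entered no gene result, 18 were at least 2-fold higher and 181 at least 2-fold lower with estradiol than in the vehicle values. With tamoxifen 32 were higher and 178 lower. At 1.5-fold, 168 were higher and 501 lower with estradiol, and 181 and 552 with tamoxifen.

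The first pattern is that both ligand arrays differed from the vehicle values in the same genes. The vehicle values may be means of 2 values, since 11.9% of them lay on steps finer than single arrays gave (0.0037% of each ligand column), and 1 of these may lie close to the baseline, since the slope of estradiol on vehicle values across genes was 1.90 (tamoxifen 1.61), although slopes depend on the unstated baseline. That would leave about 0.5 of the vehicle signal in the deposited column and make genes far from the baseline differ alike with both ligands. A response shared by both ligands stays open, and the 33.2% of the 600 shared genes (199) that passed the size rule in both comparisons with the vehicle doubled says nothing for or against it, since the genes were picked by these comparisons and both still share that vehicle. A labelling or RNA input difference cannot be told apart from the treatment with 1 array per group. The poly-A median of 1.04 with estradiol (0.47 with the vehicle doubled) does not decide the question. The spikes lay above the baseline in all columns, so a reduced vehicle signal would by itself give such a difference.

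The second pattern is that histone genes were lower on the tamoxifen array than on the estradiol array. Fewer cells in S phase would lower the G1/S list as much as the histones only if both followed S phase alike. The histone medians were -0.81 over the 8 genes of the list and -0.49 over 20 clustered histone genes. The G1/S median was 0.0697 over 26 genes, with a member SD of 0.22. Whether both follow alike within 3 h was not tested, so these values do not decide the question. Loss of 5' signal on the tamoxifen array stays open, as ACTB differed by -0.94 between its 5' and 3' probe sets and probe positions in the histone genes were not used here. An effect of tamoxifen on histone transcripts was not tested beyond these arrays.

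The third pattern is that interferon genes were lower on the tamoxifen array than on the estradiol array (median -0.42). All genes of the same brightness bands had a median of -0.0212, so the deposited values held no scaling difference of -0.42 between bands. This cannot tell of one before RMA, which may have fixed that median in advance. The hybridisation spikes differed by -0.12 (lowest -0.28) with an SD of 0.09 over 18 probe sets, which is not a spread between arrays. Their deposited values thus held no difference as large as the list's. The spikes passed through the same processing, so they cannot tell of a hybridisation difference before RMA. A smaller amplitude of the tamoxifen values stays open, as the SD across genes was 0.998 of that of the estradiol values, which speaks against one, while their slope on the vehicle values was 0.85 of the estradiol slope, which does not. A difference between the ligands stays open and untested, with 1 culture each.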

How the results depend on the processing

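The setting with the vehicle doubled and the centring within brightness bands were chosen after seeing the data. No paired analysis was possible because each group has 1 array and the results come from no test. Quantile and cyclic loess normalisation were not run, since the values are centred per probe set, and floors of 5 and 7 could not be set, since the bands have limits at 2, 4, 8 and 16. Signal over background is unknown, which limits what can be said of dim genes. Centring on the median or within bands, leaving out cross-reacting probe set types, and requiring all probe sets of a gene in the same direction left each of the 6 counts within 1.5 times its value.

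In the order estradiol higher and lower, tamoxifen higher and lower against vehicle, and tamoxifen higher and lower against estradiol, a floor of 8, which tests fewer genes, gave 290, 128, 357, 200, 62 and 80 genes. The 2-fold rule gave 144, 34, 157, 63, 12 and 34, and the rule scaled to brightness gave 197, 73, 138, 65, 99 and 111, both being stricter by construction. The mean of all probe sets gave 221 for estradiol lower, 552 for tamoxifen higher, and 102 for tamoxifen higher than estradiol; the cause was not tested. No floor, which tests more genes, gave 467 higher and 571 lower between the ligands. Doubling the vehicle gave 550 and 242 with estradiol and 870 and 450 with tamoxifen, and reduced the poly-A median with estradiol from 1.04 to 0.47 by its construction. The correlation of the ligands' differences lay between 0.64 and 0.77 over its alternatives.

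Without the cross-reacting probe set types, which leaves fewer genes, 16 list comparisons stood apart, 13 of them among the 33 that did so as reported (29 measurable) and 3 new. Of the 33, 33 still stood apart with centring on the median, 31 with centring within bands, 30 with no floor, 23 with all probe sets averaged and 17 (30 measurable) with a floor of 8. With the vehicle doubled, 8 of 17 lists with estradiol and 6 of 7 with tamoxifen still stood apart, and G1/S turned to 0.075. Of the 72 ranked genes, 30 passed with a floor of 8, which leaves fewer genes, and 69 with all probe sets averaged. Without the cross-reacting types, some ranked or always-reported genes had no probe set left above the floor. These were 10 with estradiol, 12 with tamoxifen and 10 between the ligands. A further 2 with estradiol and 1 with tamoxifen fell within 1.5-fold of vehicle. Of the ranked genes and the 6 always reported, some that were past the size rule turned direction. With estradiol these were SNCAIP (0.043, vehicle doubled) and ALMS1 (0.10, without cross-reacting types). With tamoxifen ESR1 turned (0.033 against vehicle and 0.058 against estradiol, all probe sets averaged). The cause was not tested. Within the rule, GAPDH (-0.07 to 0.008) and GPER1 (0.03 to -0.014) also turned with estradiol when the vehicle was doubled. Of other genes named, ID1 (0.01), MCM5 (0.10), AKR1C2 (-0.12), AKR1C3 (-0.55) and PSG9 (-0.11) were among those that turned with estradiol when the vehicle was doubled.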

Other observations

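The families below were picked after their values were seen and had not been fixed as lists, apart from the 8 genes of the histone list. Among 20 histone genes with names of the clustered type, 10 were at least 1.5-fold lower with tamoxifen than in the vehicle values and 9 were lower than with estradiol, with 1 higher, H1-4 (0.70). Their medians were -0.64 and -0.49, against -1.04 and -0.81 for the list. The lower ones included H2BC9 (-1.39 against vehicle, -0.78 against estradiol), H2BC6 (-1.23 and -0.67), H2BC4 (-1.21 and -0.62) and H4C8 (-0.94 and -0.68). Among histone variants encoded outside the clusters, tamoxifen minus estradiol was 0.13 for H2AZ1, 0.10 for H2AZ2, 0.02 for MACROH2A1, -0.25 for H2AX, -0.29 for H2AJ and -0.76 for H1-10. Clustered genes also held small values, such as H3C3 (-0.02), H2AC17 (0.08) and H4C5 (0.10).

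All 3 measured AKR1C genes, which encode steroid-metabolising reductases, were lower with tamoxifen than with estradiol (AKR1C1 -0.90, AKR1C2 -1.37, AKR1C3 -0.79), as were the cystatin genes CST1 (-1.46), CST2 (-1.03) and CST4 (-1.13). Members of both families resemble each other closely and can share probe signal. Against vehicle their place depended on the vehicle values: the AKR1C median was 0.91 with estradiol and 0.00 with tamoxifen as deposited, and -0.12 and -1.34 with the vehicle doubled. Of 9 MHC class II genes, 6 were higher with each ligand as deposited (medians 1.26 and 0.71), and the medians with the vehicle doubled were 0.49 and 0.03. Of the other 5 leukocyte markers measured, LCP1 (-0.45 and -0.98) passed 1.5-fold downward with tamoxifen, and CD74 (0.12 and 0.00), PTPRC (-0.40 and 0.22), CD79A (-0.14 and 0.18) and FCER1G (-0.17 and -0.02) lay within it.

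With the vehicle doubled, the largest differences with estradiol were those of CXCL2 (2.55), CXCL8 (2.52), CXCL1 (2.36), IL6 (1.75), DEPP1 (1.66) and NR4A2 (1.59), and with tamoxifen those of NR4A2 (2.34), CXCL1 (2.00), BMP2 (1.89), CXCL2 (1.89), CXCL8 (1.82), GEM (1.71) and ARRDC3 (1.69). Of 17 heat shock genes, CHORDC1 (1.03) alone passed 1.5-fold between tamoxifen and estradiol, HSPH1 stood at 0.57, HSPA4L at 0.49, HSPB1 at -0.32 and HSP90AB1 at -0.21, and the list's median was 0.07 (percentile 89.9).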
